A study of Mus musculus with 4 samples.

How the data were processed

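RNA-seq gene expression was analysed in 4 libraries from mouse B16 tumors, 1 library for each of 4 groups. The tables deposited by the authors hold raw counts, as whole numbers for 25239 gene symbols in each library, with no normalization. The submitters' processing notes name HISAT2 for alignment, featureCounts for counting and the genome build mm10, without versions. The gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads shared between paralogs, as in the MHC class I, histone, lysozyme and serpin families, can therefore be lost or assigned to either member. Groups were taken from the sample titles and treatment labels. The labels state n = 2 while each group has 1 table with 1 column, and whether mice were pooled is not stated.

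Gene positions came from the GENCODE M21 annotation of the same build, in which 24374 of the 25239 symbols were found, and 13146 of the 13357 genes compared. Erdr1 was among those without a position. The symbols Trac, Trbc1, Trbc2, Ighm and Igkc were not found among the symbols of the tables, and their lists were used without them.

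Counts were scaled with TMM factors over the 4 libraries (edgeR 4.0.16 in R 4.3.3) and expressed as CPM. Genes with a mean raw count of at least 10 over the 4 libraries were compared. Each log2 ratio has a 95% exact conditional binomial (Clopper-Pearson) interval, computed with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15. Figures were drawn with matplotlib 3.10.9. Where 1 library had 0 reads it was set to a floor of 3 counts per library and the ratio is called a bound. Such a ratio leaves out the counting error of the other library, so its interval can reach nearer to equality. No ratio was given where both libraries had 3 reads or fewer. A gene was called higher or lower when its ratio was at least 2 and its interval excluded 1. With 1 library per group no p-value across genes could be computed, and no paired analysis was possible because each group had 1 library.

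All 6 pairs of libraries were compared. In 28 gene lists, the median log2 ratio over members past the minimum count was set beside 10000 random lists of the same size, matched on mean expression in 10 bins. A percentile below 2.5 or above 97.5 is reported as outside the central 95%. This describes the 2 libraries and is not a test. Lists with fewer than 5 measured ratios have no median. The interval of a median came from 1000 Poisson draws of the counts, with draws of 0 set to the floor. The lists were melanocyte and pigment, pan T cell, cytotoxic lymphocyte, CD4 helper and regulatory T cell, naive and memory T cell, T cell checkpoint and exhaustion, NK cell, B cell and plasma cell, macrophage and monocyte, dendritic cell, neutrophil, type I interferon stimulated, interferon gamma response, MHC class I presentation, MHC class II presentation, chemokine, nucleic acid sensing and inflammatory cell death, autophagy, proliferation, hypoxia and glycolysis, fibroblast and matrix, endothelial cell, keratinocyte, skeletal muscle, adipocyte, erythroid, housekeeping reference and sex-linked genes. Some genes are in more than 1 list.

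The genes named were Tyrp1, the 10 highest and 10 lowest per comparison by the interval bound nearest to equality, and list members, as a rule those with the highest and lowest ratios. Names of unnamed gene models, pseudogenes and receptor variable segments were left out of the ranking. Some genes that this rule selects, and a test that used such a gene, are not reported here. The groups, comparisons, lists, calling rule, rule for named genes and all alternatives but 1 were chosen before the data were examined.

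The rule was tested on simulated counts with the depth of these libraries. For the MV left tumor against CTX it called 25 of 50 genes simulated at a fold of 2, 46 of 50 at 3, 50 of 50 at 4 and 49 of 49 at 8. It called 45 of 13244 unchanged genes, and 95.6% of intervals held the true ratio. For the remote tumor against CTX it called 24 of 45 at a fold of 2 and 46 of 47 at 3, and for TRP-1 T-MV against the MV left tumor 23 of 50 and 49 of 50. The simulation held counting error only, and it drew all 4 libraries from the mean levels of the 2 compared.

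The alternatives tried were DESeq2 1.42.0 size factors, total counts, upper-quartile factors, scaling on the housekeeping list, and TMM without ribosomal protein genes. The tables hold no mitochondrially encoded genes, so only ribosomal protein genes were removed there. Others were no minimum count, a mean of at least 50, a ratio of at least 4, an interval excluding a ratio of 2, thinning to the smallest total, a prior count of 2, means in place of medians, lists without shared members, and 20 bins. TMM without Rn45s, Lars2, Rpph1 and Rmrp was added after the data were seen. Alternatives planned for replicate columns were not run, since the tables have none.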

Results

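Gene expression was measured by RNA-seq in 4 libraries from B16 tumors, a transplantable mouse melanoma line, grown under the skin on both flanks of B6 mice. Treatment began on day 7 and tumors were taken 12 days after ACT, a step the labels do not expand. CTX was given the day before. The CTX library came from mice given no T cells and no virus. The MV left tumor library came from tumors injected with free virus in mice that also received TRP-1 T cells by vein. MV is written MYXV in the headers of the tables, the usual abbreviation of myxoma virus. The remote tumor library came from the uninjected right tumors of that treatment group. The TRP-1 T-MV library came from mice given TRP-1 T cells carrying the virus. TRP-1 is the melanocyte enzyme encoded by Tyrp1 (mm10 chromosome 4, 80834123 to 80851719). A group given T cells alone is described in the labels and was not analysed here. The field naming the source calls the material a melanoma cell line, whereas the extraction protocol calls it tumor tissue.

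Each group had 1 library, so there were no replicates and no test between groups. The labels state n = 2, and do not say whether RNA of several mice was pooled. Total counts were 12375526 in the MV left tumor, 14802809 in TRP-1 T-MV, 21790759 in the remote tumor and 20811605 in CTX. Reads were counted for 17232, 17436, 15951 and 15907 genes, in that order. A count of 0 allowed up to 0.222, 0.186, 0.151 and 0.156 TMM-scaled CPM. The minimum count was passed by 13357 genes, which held 99.9% of the reads. A gene was called higher or lower when its ratio was at least 2 and the 95% interval excluded equality. Intervals, given in brackets after log2 ratios, cover counting error only, not differences between animals or library preparations.

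The first comparison asked how tumors injected with free virus, in mice with TRP-1 T cells, differed from tumors after CTX alone. Immune cell genes were far higher in the MV left tumor, and pigment cell genes were lower. All 15 measured pan T cell genes were higher, with a list median log2 ratio of 5.98 [5.70, 6.64]. The pigment list had 12 of 16 members lower and none higher, with a median of −1.78 [−1.84, −1.74]. In all, 2411 genes were higher and 1488 lower.

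Tyrp1, the gene named by the T cells, had 26645 reads in the MV left tumor and 179384 in CTX, a log2 ratio of −2.25 [−2.26, −2.23]. Other melanocyte genes were lower by similar amounts. The log2 ratio was −2.45 for Mc1r, the melanocortin receptor, −2.33 for the melanoma antigen Mlana and −1.95 for the lineage factor Sox10. Kit, at 0.31, and Oca2, at −0.20, did not pass the rule. On the housekeeping scale the pigment list had 8 members lower, 1 higher and a median of −1.09.

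Among T cell genes, the costimulatory receptor Cd28 had a log2 ratio of 7.50 and the T cell receptor component Cd3e one of 6.65. Lck, a kinase of T cell receptor signalling, was the lowest of the list at 3.10, with 130 reads in CTX. All 13 measured cytotoxic lymphocyte genes were higher, with a median of 5.51. They included Ifng, the interferon gamma gene, at 8.56 [6.70, 11.61] against 2 reads, the protease gene Gzmb at 7.19 and the co-receptor Cd8a at 4.30. The CD4 helper and regulatory list had 10 of 11 members higher and a median of 4.43. Cd4 stood at 5.53 and Foxp3, the regulatory T cell factor, at 2.62, whereas Ikzf2 at 0.90 did not pass. The naive and memory T cell list had 8 of 9 members higher and a median of 5.62, with Bcl2 at 0.22 not past the rule. The checkpoint and exhaustion list had 11 of 12 members higher and a median of 4.36. Pdcd1, encoding PD-1, stood at 5.36 [3.44, 8.44] against 2 reads and Cd274, encoding PD-L1, at 2.62, while Havcr2 at −0.39 did not pass. All 3 measured NK cell genes were higher, with Klrk1 at 4.10, and the other 8 members fell below the minimum count. All 11 measured B cell and plasma cell genes were higher, with a median of 4.99 that held 4 members at their lower bound. Ms4a1, encoding CD20, had 186 reads and 0 in CTX, 88.0-fold higher at the floor of 3 counts.

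Myeloid genes were also higher. The macrophage and monocyte list had 13 of 16 members higher and a median of 2.93 [2.67, 3.22]. The integrin gene Itgam had a log2 ratio of 6.41, Arg1, encoding arginase, 6.26 and Adgre1, encoding F4/80, 6.01. C1qa at 0.21 and the mannose receptor gene Mrc1 at 0.52 did not pass. The dendritic cell list had 6 of 9 members higher, all 9 on the housekeeping scale, and a median of 3.78 that ranged from 2.26 to 4.47 over the alternatives. Its members Xcr1, Clec9a, Cd209a and Siglech fell below the minimum count. They had 13, 9, 2 and 0 reads in the MV left tumor and 2, 5, 2 and 1 in CTX. All 9 measured neutrophil genes were higher, with a median of 5.24 that held 4 members at their bound. S100a8 and S100a9, abundant in neutrophils, had only 48 and 51 reads, and Ly6g, Retnlg, Camp, Cxcr1 and Cxcr2 fell below the minimum.

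Inflammatory and antigen presentation genes followed. The chemokine list had 11 of 15 members higher and a median of 3.96. Ccl22, a ligand of CCR4, was 1179-fold higher (6648 and 8 reads, log2 ratio 10.20 [9.22, 11.42], chromosome 8, 94745590 to 94751699). The neighbouring Ccl17 (94810453 to 94812036) had 631 reads and 0 in CTX, 298-fold higher at the floor of 3 counts. The MHC class II list had 10 of 11 members higher and a median of 2.59, with the invariant chain gene Cd74 at 3.01. The MHC class I list had 11 of 14 members higher and a median of 1.33, with H2-K1 at 2.12 and the immunoproteasome gene Psmb8 at 3.27. H2-Q6 stood at 5.43, a value that reads shared with its paralogs make uncertain. The nucleic acid sensing and inflammatory cell death list had 9 of 16 members higher, 1 lower and a median of 1.86, against 11 higher and none lower on the housekeeping scale. Nlrp3, the inflammasome sensor, stood at 5.44 and Tlr3, the double-stranded RNA receptor, at −1.36. The interferon gamma response list had 8 of 20 members higher and a median of 0.82, from Nos2 at 7.00 to Irgm1 at −0.37, and on the housekeeping scale 14 higher and a median of 1.51. The type I interferon list had 6 of 23 members higher and a median of −0.02 [−0.09, 0.26], which turned to 0.67 when libraries were scaled on housekeeping genes. Irf7 at 2.95, Mx1 at 2.87 and Oas3 at 3.51 passed the rule, and Isg15 at −0.25 and Ifit2 at −0.90 did not.

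The proliferation list had 8 of 21 members lower and a median of −0.86, with Tk1 at −1.98 and Mki67 at 0.31. On the housekeeping scale that median was −0.16, with 2 members higher and 1 lower. The hypoxia and glycolysis list had 3 members higher and 5 lower of 16, against 4 and 1 on the housekeeping scale, on which its median of −0.23 turned to 0.47. The lower members included the glycolysis genes Eno1 at −1.72 and Ldha at −1.56, and the higher ones Egln3 at 2.23. Of 17 autophagy genes 1 was higher, Ulk1 at 1.35, and 1 was lower. Of 13 fibroblast and matrix genes 1 was higher and 2 were lower, with a median of 0.22. Of 11 endothelial genes 2 were higher, Kdr at 1.96 and Pecam1 at 1.75, with a median of 0.51. Of 8 skeletal muscle genes 3 were higher and 1 was lower, with a median of 0.13. On the housekeeping scale 10 type I interferon, 6 autophagy, 4 fibroblast and 5 endothelial genes were higher, and 1 fibroblast gene and no gene of the other 3 lists was lower. Both measured keratinocyte genes, Perp at 2.87 and Sfn at 1.15, were higher. The other 12 list members, Krt5 and Krt14 among them, fell below the minimum count. None of the 3 measured adipocyte genes passed, whereas 2 did with total counts and 3 on the housekeeping scale, and no erythroid gene reached the minimum count. The housekeeping list had 5 of 13 members lower and a median of −0.72, and on its own scale the median was −0.03. All 5 sex-linked genes were higher, with a median of 4.56 that held 4 members at their bound.

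Other genes were selected by rank. Il2ra, the interleukin-2 receptor alpha chain, was 569-fold higher (5611 and 14 reads, 9.15 [8.40, 10.02], chromosome 2, 11642807 to 11693193). The chemokine receptor Ccr7 was 498-fold, the siderophore-binding Lcn2 395-fold and the chemokine Cxcl3 329-fold higher. Mmp8, a neutrophil collagenase, and the cytokine Il1a each had 1 read in CTX, with log2 ratios of 11.42 [8.94, 16.72] and 10.24 [7.76, 15.55]. With 0 reads in CTX set to the floor, Plxdc2 was 233-fold and Pou2af1, a B cell coactivator, 229-fold higher. The lowest genes were Clvs1 at −5.04 [−5.92, −4.29] (chromosome 4, 9269293 to 9451691), Gsdmc, a gasdermin gene, at −4.26 [−4.45, −4.07] (chromosome 15, 63775968 to 63808759) and Aldh1a3, a retinaldehyde dehydrogenase gene, at −4.53. Fam178b stood at −4.50, Kank4 at −3.89, Afap1l2 at −3.42, Tenm4 at −3.21, Slc35f1 at −3.17, Nes, encoding nestin, at −2.95 and Mest at −2.92.

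Of 24 lists with a median, 15 lay above and 2 below the central 95% of random lists matched on expression. The housekeeping list, at percentile 2.86, lay below it as well under 7 alternatives, 6 of which were scalings that put it at 2.44 with random lists drawn anew. Scaling on housekeeping genes added 0.69 to every log2 ratio and gave 4640 genes higher and 366 lower, and scaling on total counts added 0.24 and gave 2955 and 890. In the MV left tumor, Rn45s, Lars2 and Rpph1, which take up ribosomal and other reads of RNA without a poly(A) tail, held 1.64% of the total count against 0.141% in CTX. The immune and pigment differences above lay between libraries that also differed in that share.

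**Figure D1:**
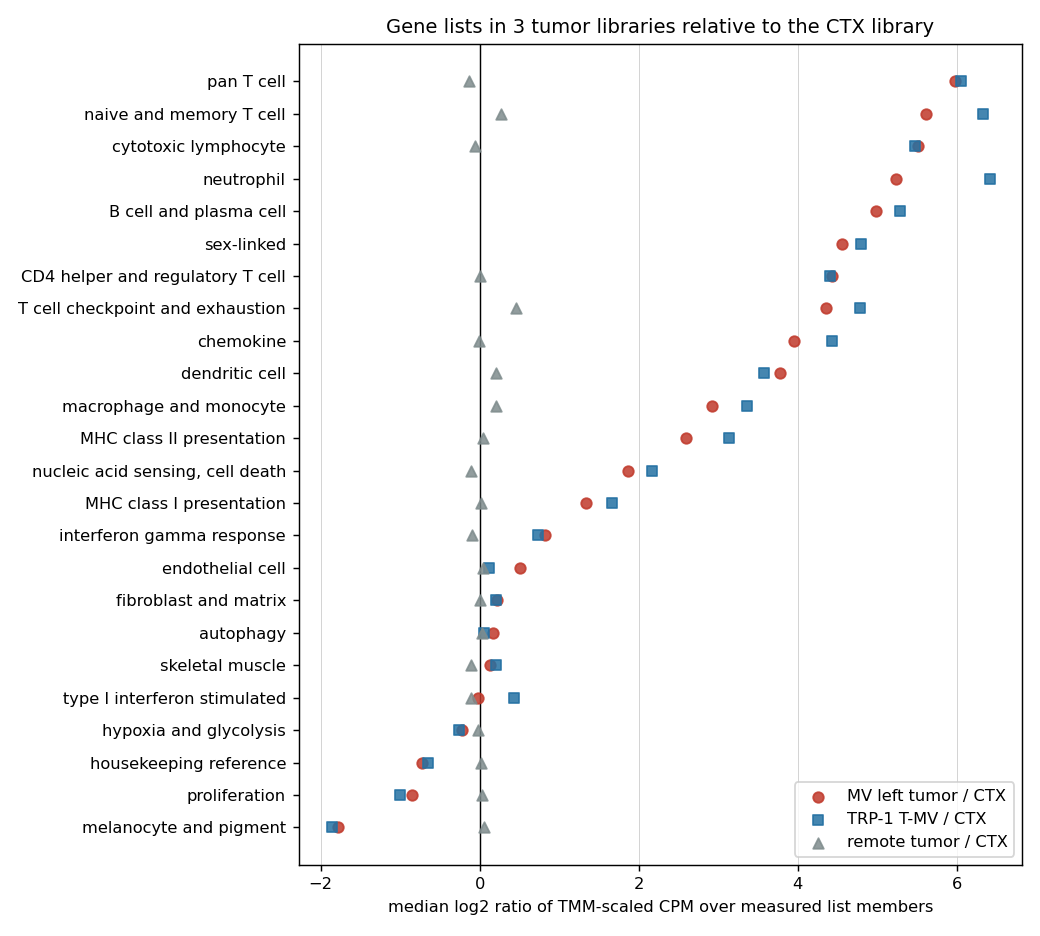
Median log2 ratio of TMM-scaled CPM over the measured members of each gene list in the MV left tumor (circles), TRP-1 T-MV (squares) and remote tumor (triangles) libraries, each over the CTX library. Pan T cell genes lie at 5.98, 6.06 and −0.14 and pigment genes at −1.78, −1.86 and 0.06; the type I interferon and hypoxia medians of the MV left tumor, the hypoxia median of TRP-1 T-MV and 10 remote tumor medians near 0 change sign with the scaling.

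The second comparison asked how the uninjected tumor, in mice with TRP-1 T cells and virus on the other flank, differed from tumors after CTX alone. Few genes differed, 61 higher and 33 lower. Of the 10 highest by interval, Ccl4 had 91 reads against 13 (log2 ratio 2.75 [1.91, 3.72], chromosome 11, 83662584 to 83664683), Tnf 143 against 24 (2.52 [1.89, 3.21]) and Cxcl2 104 against 16 (2.65 [1.88, 3.51]). Cd3e, Cd3d and Cd3g together had 17 reads in each library, and no T cell gene of the lists passed the rule.

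Ccl3 stood at 2.16 and Il1b, encoding interleukin-1 beta, at 2.62. Ptgs2, encoding cyclooxygenase 2, stood at 2.30, Acod1, encoding the itaconate-forming enzyme, at 1.95, the lipopolysaccharide co-receptor Cd14 at 1.61 and Pik3ap1 at 1.39. Endou had 9 reads and 0 in CTX, a log2 ratio of 1.53 at the floor with a lower limit of 0.93. The lower genes had few reads. They were Tmem88 at −2.22, Nup210l at −1.83, Cnksr2 at −1.77, Tlr12 at −1.58, C1ql1 at −1.28 and Zfp456 at −1.25. Stra6l had 0 reads and 7 in CTX, a log2 ratio of −1.28 at the floor with an upper limit of −0.58. Mctp1 had 1 read against 9, at −3.22 [−8.68, −0.37]. Zfp605 at −0.86 and Mfap1b at −0.74, also among the 10 lowest by interval, had ratios under 2.

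No member of the pan T cell list passed, and its median was −0.14 [−0.86, 0.26]. Neither did any member of the cytotoxic, CD4, naive and memory, checkpoint, NK cell, or B cell and plasma cell lists. The naive and memory median was 0.27 [−0.05, 0.70] and the checkpoint median 0.46 [−0.05, 0.87], both from genes with few reads. The macrophage and monocyte list had a median of 0.21 [0.07, 0.36] and 1 of 16 members higher, Adgre1 at 1.09. The dendritic cell list had a median of 0.21 [−0.33, 0.56] and 1 of 9 members higher, Itgax at 1.06, and the neutrophil list 2 of 9, Il1b and Csf3r. The chemokine list had 3 of 15 members higher, Ccl4, Cxcl2 and Ccl3, and a median of −0.01. It lay above the central 95% under 3 alternatives, at 0.17 with no minimum count and a prior count of 2, 0.54 with the mean over members and 0.37 without members shared with other lists. Nos2 at 1.60 was the only interferon gamma response gene and Nlrp3 at 2.06 the only sensing gene past the rule. The type I interferon list had none of 23 and a median of −0.11 [−0.16, −0.04]. Tyrp1 had 190866 reads, a log2 ratio of 0.04, and the only pigment gene past the rule was Ednrb at −1.18 with 11 reads against 24. In the skeletal muscle list Myh1 was lower at −1.10 with 17 reads against 35. No member passed in the MHC class I, MHC class II, autophagy, proliferation, hypoxia, fibroblast, endothelial, keratinocyte, adipocyte, housekeeping or sex-linked lists.

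Of 21 lists with a median, 4 lay above the central 95% of random lists (naive and memory, checkpoint, macrophage and monocyte, and dendritic cell) and 3 below it (pan T cell, type I interferon and interferon gamma). The counting intervals of the pan T cell, naive and memory, checkpoint and dendritic cell medians included 0. With means over members the macrophage, dendritic cell, type I interferon and interferon gamma lists lay inside and the skeletal muscle list below, and the dendritic cell list did so with no minimum count and a prior count of 2. In a simulation of this comparison 13 of 200 unchanged lists also lay outside, and the random lists were matched on a mean over all 4 libraries, to which the 2 virus-treated tumors gave most of the T cell reads. In data simulated with counting error alone, 24 of 12180 unchanged genes passed the rule. The simulation drew all 4 libraries from the mean levels of the remote tumor and CTX and compared 12359 genes, against 13357 here. Genes past the minimum count only through the virus-treated tumors were mostly absent from it, so its counts of genes and lists do not cover them. After thinning to the smallest total, 26 of the 61 higher and 9 of the 33 lower genes passed again.

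**Figure D2:**
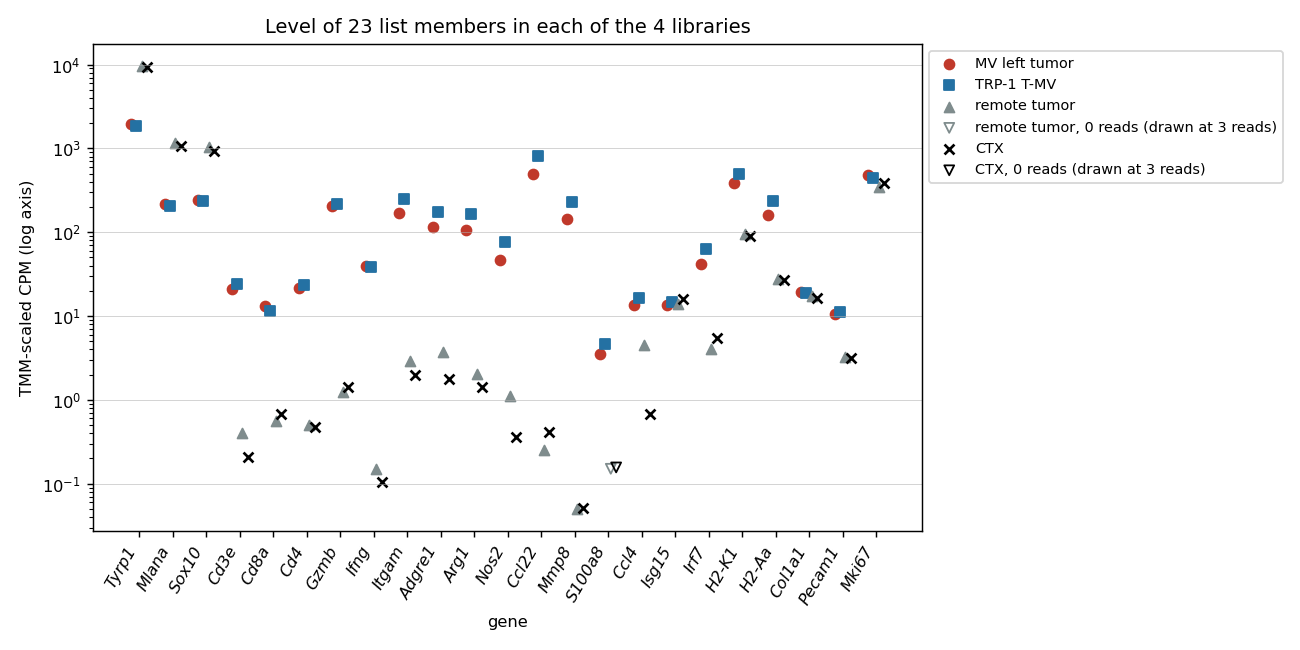
TMM-scaled CPM, on a log axis, of 23 list members in each of the 4 libraries, with open symbols at 3 reads where a library had 0. Tyrp1 lies at 1972 CPM in the MV left tumor, 1871 in TRP-1 T-MV, 9590 in the remote tumor and 9354 in CTX, and Cd3e, Gzmb, Itgam and Ccl22 lie in the opposite order of library pairs.

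The third comparison asked how tumors of mice given T cells carrying the virus differed from tumors after CTX alone. Immune cell genes were higher in TRP-1 T-MV and pigment genes lower. All 15 pan T cell genes were higher, with a median of 6.06 [5.71, 6.61]. So were all 9 measured neutrophil genes, with a median of 6.42 [6.26, 6.67] that held 4 members at their bound. Ly6g, Retnlg, Camp and Cxcr2 of that list, below the minimum count, had 3, 1, 10 and 7 reads in TRP-1 T-MV. Tyrp1 had 30127 reads and a log2 ratio of −2.32 [−2.34, −2.30]. The pigment list had 12 of 16 members lower and a median of −1.86, against 11 lower, 1 higher and −1.21 on the housekeeping scale. In all, 2476 genes were higher and 1559 lower.

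Lymphocyte lists had medians of 5.47 for the 13 cytotoxic genes, all higher, 4.41 for CD4 helper and regulatory genes (10 of 11 higher), 6.33 for naive and memory genes (8 of 9), 4.79 for checkpoint genes (11 of 12) and 5.29 for B cell and plasma cell genes (11 of 11, 4 at their bound). All 3 measured NK cell genes were higher, and the other 8 members, Ncr1 and Klrb1c among them, fell below the minimum count. Gzmb stood at 7.27, Ifng at 8.54 [6.68, 11.59] against 2 reads and Cd8a at 4.07. The macrophage and monocyte list had 14 of 16 members higher and a median of 3.36, with Itgam at 6.99, Arg1 at 6.89 and C1qa at 0.53. The dendritic cell list had 7 of 9 higher, all 9 on the housekeeping scale, and a median of 3.58 that ranged from 1.49 to 4.23 over the alternatives. Its members Xcr1, Clec9a, Cd209a and Siglech, below the minimum count, had 8, 5, 3 and 1 reads in TRP-1 T-MV. Chemokines had 11 of 15 higher and a median of 4.43, MHC class II genes 10 of 11 and 3.14, and MHC class I genes 11 of 14 and 1.66. The sensing list had 10 of 16 higher, 1 lower and a median of 2.17, against 12 higher and none lower on the housekeeping scale. The interferon gamma list had 9 of 20 higher and a median of 0.74, against 14 and 1.39 on the housekeeping scale. The type I interferon list had 10 of 23 higher and a median of 0.44 [0.23, 0.60], with Oas3 at 4.05, Irf7 at 3.53, Isg15 at −0.11 and Cmpk2 at −0.97.

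The proliferation list had 10 of 21 members lower and a median of −0.9996, against 1 lower and −0.35 on the housekeeping scale. Hypoxia and glycolysis genes had 3 higher and 5 lower of 16, against 5 and 1 on that scale, on which their median of −0.26 turned to 0.39. Autophagy genes had 1 higher and 1 lower, fibroblast genes 1 higher and 2 lower, endothelial genes 2 higher and skeletal muscle genes 2 higher. Both measured keratinocyte genes were higher. On the housekeeping scale 12 type I interferon, 7 autophagy, 5 fibroblast and 4 endothelial genes were higher, and 1 fibroblast gene and no gene of the other 3 lists was lower. No adipocyte gene passed, whereas 1 did with total counts and all 3 on the housekeeping scale. The housekeeping list had 5 of 13 lower, and all 5 sex-linked genes were higher with a median of 4.80, 4 at their bound.

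Among genes chosen by rank, Ccl22 was 1936-fold higher (10.92 [9.94, 12.13]), Ccr7 733-fold, Lcn2 607-fold, Il2ra 573-fold and Cxcl3 549-fold. Mmp8 stood at 12.10 [9.62, 17.40] and Il1a at 10.99 [8.51, 16.30], each against 1 read. With 0 reads in CTX set to the floor, Ccl17 was 445-fold, Plxdc2 360-fold and Fpr1, a formyl peptide receptor gene, 317-fold higher. The lowest genes were Gsdmc at −4.19 [−4.36, −4.02], Fam178b at −4.46, Kank4 at −4.14, Aldh1a3 at −4.13, Clvs1 at −3.89, the cation channel gene Mcoln3 at −3.84, Slc35f1 at −3.39, Megf6 at −3.23 and Nes at −3.12. Prkg2 had 0 reads and 38 in CTX, 10.6-fold lower at the floor.

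Of 24 lists, 16 lay above and 2 below the central 95% of random lists. The type I interferon list, among those above, lay inside with means over members and without members shared with other lists. Housekeeping scaling added 0.65 to every log2 ratio and gave 4371 genes higher and 431 lower, and total counts added 0.24 and gave 2973 and 931. Rn45s, Lars2 and Rpph1 held 1.62% of the total count in this library, a share that differed from that of CTX in the same direction as the immune lists.

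The fourth comparison set the injected against the uninjected flank of the same treatment group. Immune genes were higher and pigment genes lower in the injected MV left tumor. The pan T cell median was 6.42 [5.91, 6.99], with all 15 members higher, and the pigment median −1.80 [−1.84, −1.76], with 12 of 16 lower, and −1.04 on the housekeeping scale. Tnfrsf8, encoding CD30, had 848 reads against 1 (10.29 [7.80, 15.59]), and Irf4, a lymphocyte transcription factor gene, 1218 against 3 (9.22 [7.67, 11.50]). In all, 2483 genes were higher and 1567 lower.

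Tyrp1 stood at −2.28. Ccl22 was at 10.94, Il2ra at 10.21, Mmp8 at 11.47 [8.99, 16.78] against 1 read, Lcn2 at 8.39, the arginine transporter gene Slc7a2 at 7.99 and Cxcl3 at 7.79. With 0 reads in the remote tumor set to the floor, Ccl17 was 310-fold and Pou2af1 238-fold higher. Gsdmc was at −4.28, Clvs1 at −4.85, Aldh1a3 at −4.58, Fam178b at −4.42, Kank4 at −3.75, Slc35f1 at −3.05, Mest at −3.03, Dagla at −2.91 and the tubulin gene Tubb3 at −2.81. Dync1i1 had 3 reads against 85, at −4.27 [−6.57, −2.67]. The list medians were 5.33 for cytotoxic genes, 5.30 for neutrophil genes, 2.98 for macrophage and monocyte genes (12 of 16 higher), 2.25 for chemokines and 0.24 for type I interferon genes (7 of 23 higher). The proliferation median was −0.77, with 8 of 21 lower, and −0.02 on the housekeeping scale. The hypoxia median of −0.15 turned to 0.60 on the housekeeping scale.

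In this comparison 15 of 24 lists lay above and 3 below the central 95% of random lists. The housekeeping list, among those below, lay inside with means over members and with 20 bins. Housekeeping scaling added 0.75 to every log2 ratio and gave 5069 genes higher and 333 lower, and total counts added 0.26 and gave 3106 and 902. The share of Rn45s, Lars2 and Rpph1 was 0.164% in the remote tumor.

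The fifth comparison set virus carried by T cells against the tumor of T cell treated mice that received no virus itself. Immune genes were again higher in TRP-1 T-MV and pigment genes lower. The pan T cell median was 6.43 [5.93, 7.04], the neutrophil median 6.46 and the macrophage and monocyte median 3.47, with 14 of 16 higher. The pigment median was −1.94, or −1.23 on the housekeeping scale, and Tyrp1 stood at −2.36. In all, 2514 genes were higher and 1622 lower.

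Ccl22 was at 11.65, Il2ra at 10.22, Mmp8 at 12.15 [9.67, 17.46] and Tnfrsf8 at 10.26 [7.78, 15.57], the last pair against 1 read each. Irf4 was at 9.23 [7.68, 11.51] against 3 reads, Lcn2 at 9.01, Slc7a2 at 8.58 and Cxcl3 at 8.53. With 0 reads in the remote tumor set to the floor, Ccl17 was 462-fold and Pou2af1 223-fold higher. The lowest genes were Gsdmc at −4.21, Fam178b at −4.38, Aldh1a3 at −4.18, Kank4 at −4.002, Mcoln3 at −3.78, Clvs1 at −3.70, the oncogene Lmo1 at −3.43, Megf6 at −3.28, Slc35f1 at −3.27 and Mest at −3.10. The type I interferon list had 10 of 23 higher and a median of 0.51, MHC class II genes had a median of 3.08, MHC class I genes 1.65 and chemokines 2.57. The proliferation median was −0.94, with 9 of 21 lower, and −0.23 on the housekeeping scale, on which the hypoxia median of −0.19 turned to 0.52.

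Here 16 of 24 lists lay above and 3 below the central 95%. The housekeeping list, among those below, lay inside with means over members and with 20 bins, and the type I interferon list, among those above, with means. Housekeeping scaling added 0.71 to every log2 ratio and gave 4765 genes higher and 386 lower, and total counts added 0.25 and gave 3089 and 958.

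The sixth comparison set virus delivered by T cells against virus injected into the tumor. No T cell, macrophage or dendritic cell gene of the lists passed the rule, and 2 of 9 neutrophil genes did. The pan T cell median was −0.01 [−0.08, 0.07] and turned to just above 0 with DESeq2 size factors. The neutrophil median was 0.65 [0.50, 0.75], the MHC class II median 0.51 [0.44, 0.55] and the macrophage and monocyte median 0.44 [0.37, 0.55]. The neutrophil genes Ly6g, Retnlg, Camp, Cxcr1 and Cxcr2 were below the minimum count and not part of the neutrophil median. Only 75 genes were higher and 29 lower.

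Of the macrophage and monocyte genes 15 of 16 had a log2 ratio above 0, as did all 11 MHC class II and all 14 MHC class I genes. The type I interferon list had 21 of 23 above 0, none past the rule, and a median of 0.22 [0.16, 0.32]. The dendritic cell median was 0.64 [0.10, 0.69], with 5 of 9 members above 0, and ranged from 0.18 to 0.65 over the alternatives. Xcr1, Clec9a, Cd209a and Siglech were below the minimum count and not part of it. The chemokine median was 0.47, the checkpoint median 0.27, the sensing median 0.24, the MHC class I median 0.14 and the hypoxia median 0.06. In the neutrophil list S100a9 at 1.20 and Trem1, an amplifying receptor of myeloid cells, at 1.17 passed the rule. In the chemokine list Cxcl12 was lower at −1.53, with 7 reads against 17. The cytotoxic, CD4 and interferon gamma medians were each −0.02, the B cell and plasma cell median was 0.05 and the naive and memory median 0.03, which turned to −0.01 on the housekeeping scale. The pigment median was −0.08 and the proliferation median −0.09, both below the central 95% of random lists. Tyrp1 stood at −0.08 [−0.10, −0.05].

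Tnfsf13b, encoding the B cell survival factor BAFF, had 103 reads against 29 (1.58 [0.97, 2.22], chromosome 8, 10006467 to 10039072), and Trem2, a receptor of macrophages, 414 against 166 (1.07 [0.80, 1.33]). Erdr1 stood at 1.09. H2-M2 at 0.99, Ccl2 at 0.79, Cxcl3 at 0.74, Ccl22 at 0.72 and Csf2rb at 0.72 had ratios under 2. Lyz1 had 9 reads against 67 (−3.15 [−4.34, −2.14], chromosome 10, 117287797 to 117292868), and Serpina1a 3 against 16 (−2.67 [−5.09, −0.86]); reads shared with close paralogs make both values uncertain. Tulp2 at −1.45, Hspb7 at −1.38, Scn1a at −1.15, Nxpe4 at −1.11 and Sox21 at −1.08 passed the rule on few reads, and Inpp1 at −0.92 did not pass.

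Of 24 lists, 9 lay above and 2 below the central 95% of random lists. With means over members the dendritic cell and pigment lists lay inside and the naive and memory and interferon gamma lists above, and the dendritic cell list also lay inside with no minimum count and a prior count of 2. In data simulated with counting error alone, 52 of 13651 unchanged genes passed the rule, and with an interval that had to exclude a ratio of 2 no gene was higher and 1 was lower.

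**Figure D3:**
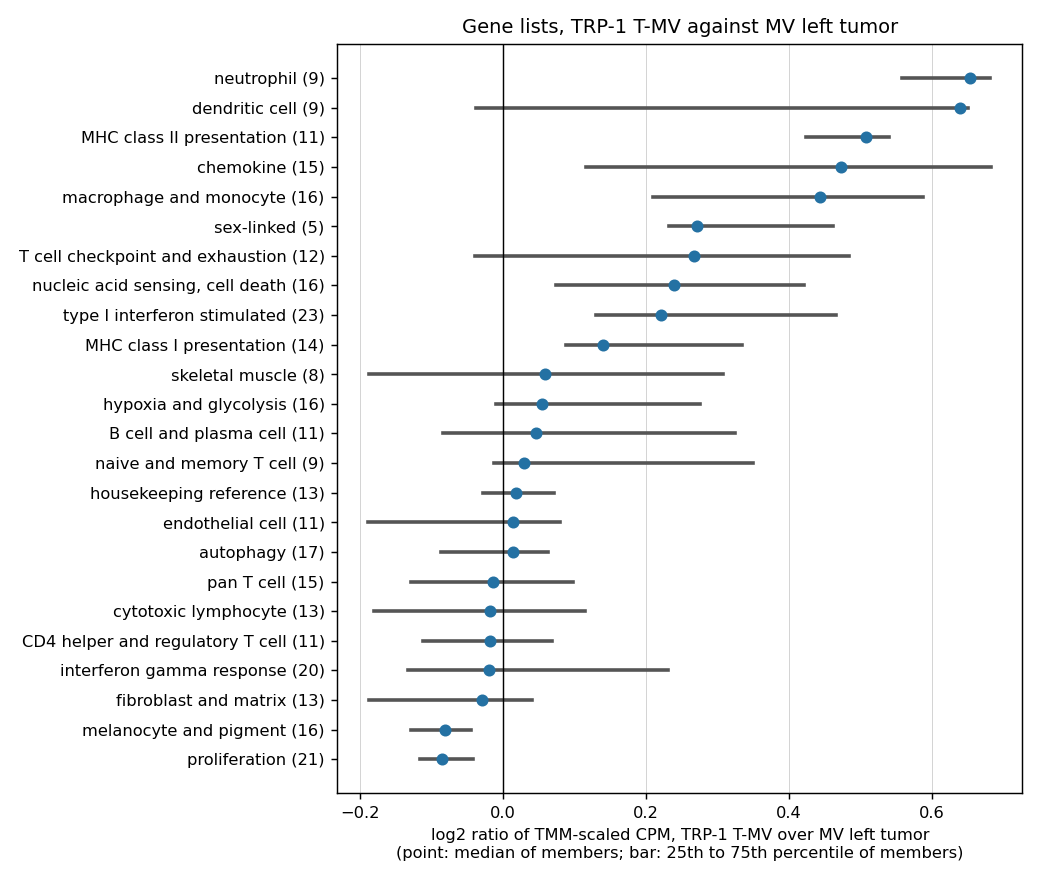
Median log2 ratio of TMM-scaled CPM, TRP-1 T-MV over MV left tumor, for each gene list (points), with the 25th to 75th percentile of its members (bars) and the number of measured members in brackets. Neutrophil genes lie at 0.65 and MHC class II genes at 0.51, whereas pan T cell genes lie at −0.01, a sign that turns with the scaling, as do those of the naive and memory, autophagy, endothelial and housekeeping lists.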

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

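Both tests of Y-linked reads were chosen after the results were seen. The histone test was fixed beforehand.

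Reads of Rn45s, Lars2 and Rpph1 stood out because their share lay above the level of the CTX control in genes no comparison was about. They held 1.6440% of the total count in the MV left tumor and 1.6232% in TRP-1 T-MV, against 0.1641% in the remote tumor and 0.1406% in CTX. Replication-dependent histone genes, whose mRNA lacks a poly(A) tail, had median log2 ratios of 3.052 and 3.191 against CTX over 26 genes, so less selection for polyadenylated RNA in these 2 libraries is a candidate explanation. A difference in library preparation or RNA quality between the 2 pairs of libraries remains open. So does the treatment itself, which against CTX was virus together with T cells. The labels give no batch, no test separated these, and the immune and pigment differences follow the same pairs.

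Reads of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty stood out because CTX had 0, against 291 in the MV left tumor, 449 in TRP-1 T-MV and 2 in the remote tumor. From the reads of the leukocyte gene Ptprc (1909, 2372, 52 and 64 in the MV left tumor, TRP-1 T-MV, remote tumor and CTX), 20.1 Y-linked reads were expected in the remote tumor and CTX together if male leukocytes made up one share of leukocytes in all tumors, and 2 were counted. The exact Poisson probability of 2 or fewer was 4.35e-07, which covers counting error only, and with 1 library per group this explanation stays open. Transferred T cells from male donors could also bring such reads, but the remote tumor had no Cd3e, Cd3d and Cd3g reads above the CTX level, so 0.000 were expected there and this cannot be told apart. Xist, expressed from the inactive X chromosome of female cells, had 504, 553, 48 and 31 reads in the same order, and no biological explanation was tested further.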

How the results depend on the processing

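The alternative without Rn45s, Lars2, Rpph1 and Rmrp was chosen after the data were seen, and it kept all 12 counts of genes within 1.5 times. So did DESeq2 size factors, upper-quartile factors, TMM without ribosomal protein genes, and thinning. Of 132 counts of genes, 89 stayed within 1.5 times and 43 moved. Of 1410 list medians under an alternative, 1189 kept their value within counting error. That total includes 141 under 20 bins, which changes only the random lists and cannot move a median. All 141 were also kept by TMM without ribosomal protein genes, and by TMM without Rn45s, Lars2, Rpph1 and Rmrp. Housekeeping scaling kept 48 of 141, means over members 94 and total counts 97, and the other alternatives kept 118 to 140. The sign changed in 46 of the 1410 medians, 17 of them with housekeeping scaling, but in only 1 whose list lay outside the central 95%. Of 12096 values of named genes and list members, 10357 kept theirs and 1739 moved. The sign changed in 360, 238 of them with housekeeping scaling. The sign changed for no gene that had passed the rule, an outcome that the settings fixed. No scaling moved a log2 ratio by more than 0.753, which is less than the ratio of 2 that the rule requires. A prior count moves ratios toward equality without turning them. The comparisons are given in the order MV left tumor against CTX, TRP-1 T-MV against CTX, MV left tumor against remote tumor, and TRP-1 T-MV against remote tumor, followed by remote tumor against CTX and TRP-1 T-MV against MV left tumor.

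Housekeeping scaling gave 4640, 4371, 5069 and 4765 genes higher and 366, 431, 333 and 386 lower in the first 4. Total counts gave 890, 931, 902 and 958 lower. Both move every ratio of a comparison by one amount, and why the housekeeping genes were lower was not tested. A mean count of at least 50, which compares fewer genes, gave 1540, 1575, 1604 and 1616 higher in the first 4, 31 higher and 9 lower in the fifth, and 10 higher and 3 lower in the sixth. A ratio of at least 4, stricter by construction, gave 1457, 1497, 1424 and 1463 higher and 226, 240, 230 and 245 lower, then 16 higher and 4 lower, and 4 higher and 2 lower. An interval excluding a ratio of 2 gave 885, 961, 965 and 1022 lower, then 7 higher and 0 lower, and 0 higher and 1 lower. Without a minimum count the fifth had 60 lower, and the sixth 127 higher and 67 lower, since more genes were compared. In the sixth, with means over members, 1 list lay below the central 95% in place of 2, and the cause was not tested. The dendritic cell median of the remote tumor against CTX, 0.21, reversed to −0.0268 with no minimum and a prior count of 2, and the cause was not tested.

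A count of 0 allowed up to 0.222, 0.186, 0.151 and 0.156 TMM-scaled CPM in the MV left tumor, TRP-1 T-MV, remote tumor and CTX, and lower levels were not detectable. After thinning, 51 genes were higher and 32 lower in the fifth, 26 and 9 of them shared with the full depth, and 69 and 21 in the sixth, 56 and 17 of them shared. Thinning also redraws counting noise. With 1 library per group no library could be left out, and alternatives for replicates were not run.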

Other observations

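The genes of the next 2 paragraphs were chosen after their values were seen. Of the 4 tests on leukocyte lists below, those of scaling, of the melanoma cell share and of RNA preparation were chosen after the results were seen, and that of length and GC content before.

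Other immune genes were higher in both virus-treated tumors. Mmp12, macrophage elastase, had 8018 reads in the MV left tumor, 14863 in TRP-1 T-MV, 85 in the remote tumor and 74 in CTX, with log2 ratios to CTX of 7.26 and 7.90. Chil3, a chitinase-like gene of macrophages, stood at 6.97 and 7.53. Pf4, encoding platelet factor 4, stood at 6.13 and 6.75, and Ppbp, another platelet gene, had 198 and 347 reads and 0 in both other libraries. The costimulatory ligand genes Cd80 and Cd86 stood at 6.15 and 6.22 in the MV left tumor, and Tnfrsf9, encoding 4-1BB, at 5.97. Ccr4, the receptor of Ccl22 and Ccl17, had 166 and 220 reads and 0 in the remote tumor and CTX. Il6 had 115, 218, 1 and 2 reads and Il10 125, 104, 1 and 1, in the order MV left tumor, TRP-1 T-MV, remote tumor and CTX. Il4 and Il17a had 0 in all 4.

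Some genes of blood and stroma had few or no reads. The globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, whose reads can be shared between paralogs, were listed at 0 in all 4 libraries. Alas2, another gene of the erythroid list, had 3, 3, 4 and 8 reads in the MV left tumor, TRP-1 T-MV, remote tumor and CTX. Slc4a1 had 1, 1, 0 and 0. The endothelial gene Cldn5 had 0, 3, 5 and 1 reads in that order, and the matrix gene Lum 7, 14, 3 and 3. The tissue macrophage gene Vsig4 had 0 in all 4, and Cd163 0, 1, 0 and 3. Col1a1 had 260, 305, 349 and 316 reads. The 13 measured fibroblast and matrix genes had a summed CPM of 732, 747, 1588 and 1613 and the 11 endothelial genes one of 339, 342, 608 and 578.

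The libraries fell into 2 close pairs. Among genes with at least 100 reads in both libraries compared, the robust SD of the log2 ratio was 0.122 for the remote tumor against CTX and 0.122 for TRP-1 T-MV against the MV left tumor, 1.87 and 1.57 times the counting SD. It was 0.726 for the MV left tumor against the remote tumor, which came from one treatment group.

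The pan T cell, cytotoxic, B cell, macrophage, dendritic cell and neutrophil lists were higher in the MV left tumor and TRP-1 T-MV than in CTX. Under all scalings run their lowest median was 2.919, of macrophage and monocyte genes in the MV left tumor with ribosomal protein genes left out. Each scaling adds one amount to every log2 ratio, and the lowest amount here was −0.0064. That outcome therefore followed from the medians already seen. The choice among the scalings run does not explain these medians, and other scalings were not tried. The pan T cell median exceeded that of 24 endothelial and fibroblast genes. The 95% bootstrap interval of the log2 difference began at 5.299 in the MV left tumor and 5.319 in TRP-1 T-MV. That interval resamples list members within single libraries and covers no difference between animals or preparations. The summed CPM of both the endothelial and the fibroblast list was lower in these 2 libraries than in CTX, as was that of the pigment list. A sum is weighted toward highly expressed genes. The median log2 ratio of the 24 endothelial and fibroblast genes, by contrast, was 0.254 in the MV left tumor and 0.162 in TRP-1 T-MV. Whether those genes were read from cells other than melanoma cells was not tested, so a lower share of melanoma cells alone cannot be decided on. After correction for transcript length and GC content the median over 73 members of the leukocyte lists was 5.362 and 5.695. The median over these 73 members exceeded that of 32 endothelial, fibroblast and muscle genes. The 95% bootstrap interval of that log2 difference, again over list members, began at 4.242 and 4.626. A difference in RNA preparation that acts alike on both sets of genes would leave no such difference between them. The list medians had been seen before this test was chosen, so it is no independent evidence on RNA preparation. A preparation difference that acts more on some genes or cell types than on others was not tested. A lower share of melanoma cells and a preparation difference that acts unevenly stay open. So do lymphoid tissue sampled with the tumor, and different sampling or handling of the 2 pairs of tumors. Transferred TRP-1 T cells, and immune cells drawn by the virus or the T cells, stay open as well, since CTX mice received neither. The design cannot separate these possibilities.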
